A study of Mus musculus with 24 samples.

How the data were processed

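RNA was sequenced from macrophages purified from the lungs of wild-type C57 mice in 24 libraries, prepared per the labels' protocols with an NEBNext Ultra RNA kit. The labels place the libraries in 7 groups. These are naive TRAM (n = 4), TRAM and TransAM 7 days after infection with Streptococcus pneumoniae (SP; n = 4 each), TRAM and TransAM 14 days after infection (n = 3 each), and cells taken 28 days after PBS or SP (n = 3 each). TRAM and TransAM are population names of the labels, which do not spell them out, and the day 28 labels name no population. The labels do not say that replicates come from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

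The deposited values are raw counts per gene in 2 tables, 1 of 18 libraries (naive, day 7 and day 14) and 1 of 6 (day 28). Per the submitters' processing notes, the authors counted reads with featureCounts 1.5.0-p3 on the mouse build mm10 and used R 4.1.2 with DESeq2 1.34.0. The aligner, the strand setting and the annotation release are not given in the sources used here, so reads of overlapping, antisense and near-identical genes cannot be told apart, and values of multigene families such as the MHC, interferon-response and immunoglobulin genes are uncertain to that extent. Both tables list the same 54532 genes. Of these, 54409 were found in GENCODE M21, and 98.3% of those found had the same coordinates and strand there. Totals ran from 13694181 to 18327376 counts per library. No 2 replicates of a group held identical counts, and all 30 pairs of replicates differed by more than sampling noise (lowest chi-square per degree of freedom 4.06). The highest was 60.06, between PBS replicates 1 and 2 of day 28.

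Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 14036 genes in the first table and 13314 in the day 28 table. Counts were scaled by TMM and fitted by edgeR's quasi-likelihood model with group as the only term, over the 18 libraries together and over the 6 day 28 libraries alone. Each of the 10 comparisons was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Values are log2 fold changes ± SE from that fit, and counts scaled to the library total (CPM) are given as mean ± SD. Because the tables were normalized separately, tests were run only within a table, and levels set across the tables compare libraries that were never scaled together. Ratios of summed counts carry exact 95% binomial intervals, which cover counting error only.

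In all, 32 lists of genes for pathways, cell states and cell types were tested with camera (correlation preset to 0.01) and fry, adjusted over the lists of a comparison. camera compares a list with all other genes. fry's directional test asks whether the genes of a list move, on balance, in 1 direction, and makes no comparison with other genes. camera was also run with a correlation estimated from the data. Summed CPM of marker lists of other cell types were given per group. For day 28, 4 sets of 200 genes were taken from the other table: those with the largest rise and fall in day 14 TransAM against TRAM, and in day 14 TRAM against naive TRAM.

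The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 genes of largest rise and the 8 of largest fall (adjusted p under 0.05, mean log2 CPM of 3 or more, no overlap between the groups), up to 4 members of smallest adjusted p per list, fixed sentinel genes of senescence, identity, lipid and inflammatory programmes, and the most abundant markers of other cell types. The alternatives were DESeq2's size factors, a DESeq2 1.42.0 Wald test, limma-voom with quality weights, no count filter, a CPM filter of 1, protein-coding genes only, a fit of only the groups compared, an added fold threshold, the replicate number as a block, and leaving out each library in turn. No deposited column was left out.

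The tests were run first on simulated counts with the real means and library sizes and 200 changed genes. For day 7 TRAM against naive TRAM (14036 genes), edgeR recovered 59.7%, 62.9% and 92.6% of genes changed 1.5-, 2- and 4-fold, and 7.69% of its 156 calls were false. For day 14 TransAM against TRAM it recovered 41.5%, 68.8% and 94.4%, with 6.12% false. For the change of that difference between days it recovered 34.9%, 67.3% and 89%, with 3.65% false. For day 28 (13314 genes) it recovered 28.4%, 69.2% and 89.7%, with 6.02% false.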

Results

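Alveolar macrophages were profiled by RNA sequencing after pneumonia caused by Streptococcus pneumoniae (SP), in a series whose title concerns senescence of resident cells and their displacement by monocytes. TRAM came from naive mice (n = 4) and from mice 7 days (n = 4) and 14 days (n = 3) after infection, and TransAM from the same infected time points (n = 4 and n = 3). Cells from 28 days after PBS or SP (n = 3 each) carry no population name. Total counts per library were 14208114 to 17497505 in naive TRAM, 14422732 to 14625574 in day 7 TRAM and 13694181 to 17349694 in day 7 TransAM. They were 14376263 to 14879229 in day 14 TRAM, 14946962 to 15923700 in day 14 TransAM, 17307225 to 18327376 after PBS at day 28 and 15131265 to 16855002 after SP at day 28. The first principal component of the naive to day 14 libraries held 77.8% of the variance and ran from naive TRAM through infected TRAM and day 14 TransAM to day 7 TransAM.

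**Figure D1:**
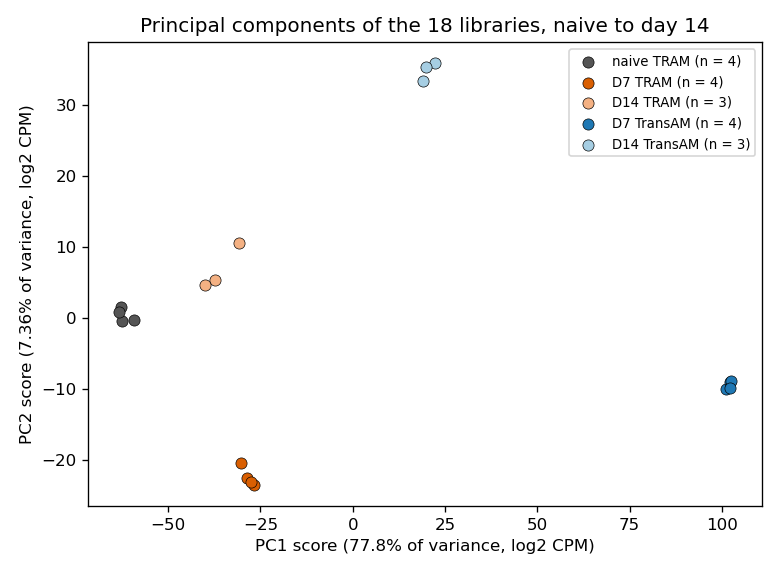
Scores of the 18 naive to day 14 libraries on the first 2 principal components of log2 CPM, 1 point per library, coloured by group. Day 7 TransAM lie above 101 on the first component, day 14 TransAM between 19.2 and 22.2, and all TRAM below 0.

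The comparison of day 7 TRAM with naive TRAM asked how this population differed after infection (n = 4 against 4). The labels give naive TRAM no day and no PBS. In every comparison with naive TRAM, the time of collection and the handling therefore cannot be told apart from infection. Mmp14, a membrane-bound matrix metalloprotease, rose by 8.59 ± 0.27 on the log2 scale (± SE here and below), from 0.284 ± 0.206 to 112 ± 22 CPM. The chemokine gene Cxcl16 rose by 4.01 ± 0.15 and the interleukin receptor gene Il21r by 6.27 ± 0.47. Tlr5, the flagellin receptor, fell by 3.32 ± 0.25, the fatty acid transporter gene Cd36 fell by 2.62 ± 0.18, and the lipid carrier gene Fabp1 fell by 2.42 ± 0.10. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1976 of 14036 genes were higher and 1498 lower.

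Cell-cycle genes fell as a group in day 7 TRAM. Of 50 cell-cycle and DNA replication genes, 46 fell and 1 rose (47 and 1 adjusted over the list alone), with a median log2 change of -0.72 and a camera adjusted p of 2.08e-29. The microtubule regulator Stmn1 fell by 1.15 ± 0.09, the mitotic kinesin Kif23 fell by 1.09 ± 0.09, the replication helicase subunit Mcm5 fell by 1.09 ± 0.09, and the proliferation marker Mki67 fell by 0.82 ± 0.16. Of 41 DNA damage and repair genes, 18 fell and none rose (20 fell adjusted over the list alone; camera adjusted p = 4.65e-08), among them Lig1 at -1.02 ± 0.10 and Brca1 at -1.10 ± 0.12.

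Among genes of cell-cycle arrest and senescence, Cdkn2a and Cdkn2b were higher in day 7 TRAM than in naive TRAM. Both encode INK4-family inhibitors of cyclin-dependent kinases, and both lie on chromosome 4 of mm10, Cdkn2a from position 89274471. Gene-level counts do not separate the INK4A and ARF products of Cdkn2a. Cdkn2a rose by 1.81 ± 0.39 (adjusted p = 0.00099) from 40 to 122 summed counts, a CPM ratio of 3.57 (exact 95% interval 2.48 to 5.23). Cdkn2b rose by 1.97 ± 0.35 (adjusted p = 0.00013) from 72 to 245 counts, a ratio of 3.98 (3.05 to 5.25). Cdkn1a, the p53-induced cell-cycle inhibitor, had a log2 change of -0.04 ± 0.09 (adjusted p = 0.77), and Lmnb1, a nuclear lamina gene that is low in senescent cells, fell by 0.60 ± 0.11. Of 31 arrest and senescence genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone), which camera did not call against other genes (adjusted p = 0.236) and fry called up on balance (adjusted p = 0.000475). Of 34 p53 targets, 9 rose, among them Plk2 by 1.61 ± 0.18, and 6 fell, among them Pidd1, which fell by 0.88 ± 0.12 (9 and 6 adjusted over the list alone; camera adjusted p = 0.578; fry, up, adjusted p = 0.0336). Of 45 genes for senescence-associated secretory factors, 23 rose and 2 fell (27 and 3 adjusted over the list alone; camera adjusted p = 2.46e-09), with Timp2 up by 1.34 ± 0.08 and Cxcl16 as given above.

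**Figure D2:**
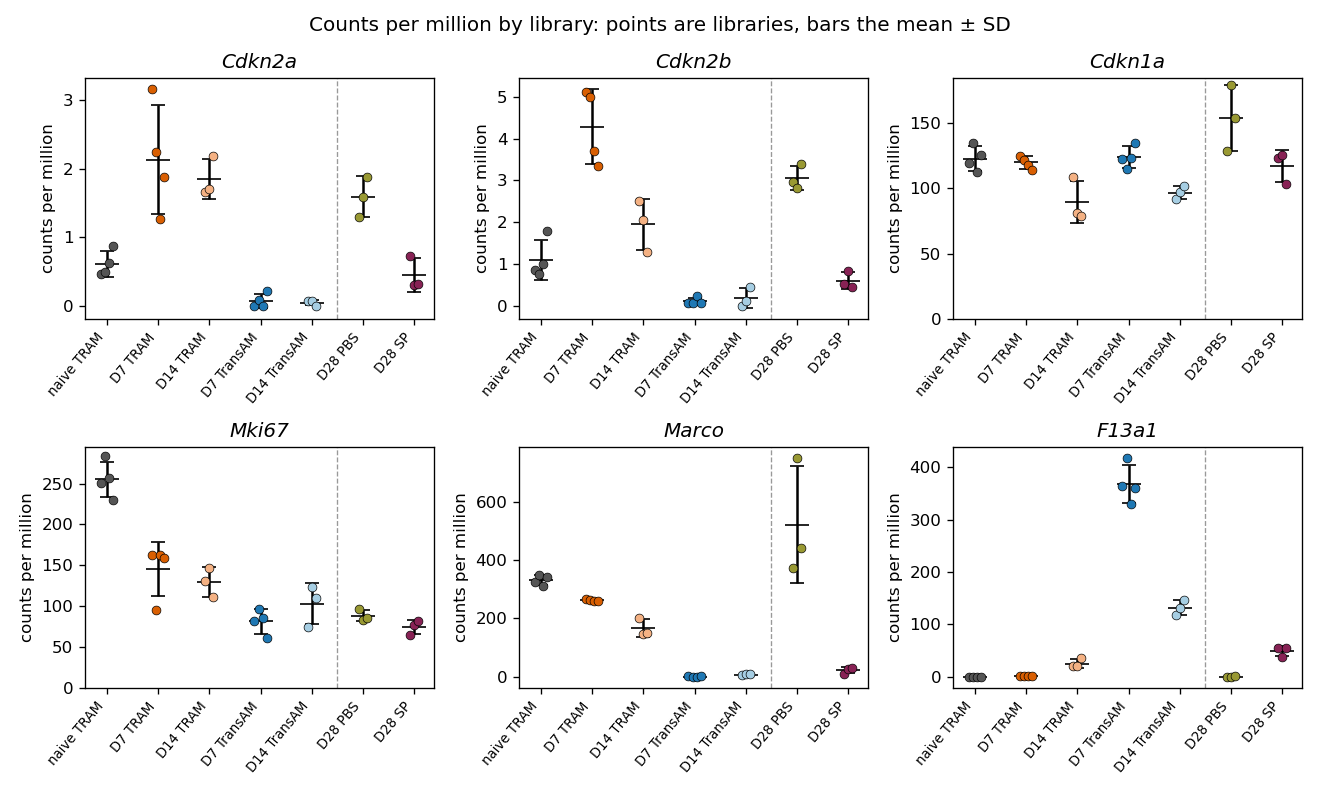
CPM of 6 genes in every library, with bars for mean ± SD per group; the dashed line separates the day 28 libraries, which were normalized apart. Cdkn2a averaged 0.609 CPM in naive TRAM, 2.13 in day 7 TRAM and 0.0742 in day 7 TransAM.

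Immune and lipid genes of day 7 TRAM moved in groups as well. Of 45 type I interferon-response genes, 35 rose (38 adjusted over the list alone; camera adjusted p = 1.83e-17), with Ifi209 up by 3.50 ± 0.23 and Oas2 by 2.46 ± 0.16. Of 16 MHC class II genes, 12 rose (12 adjusted over the list alone; camera adjusted p = 2.31e-09), with Cd74 up by 3.36 ± 0.22 and H2-Aa by 3.34 ± 0.24. Of 34 inflammatory genes, 21 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 4.23e-10), with the cytokine gene Il1b up by 3.09 ± 0.37 and the neutrophil chemoattractant gene Cxcl2 by 3.58 ± 0.43, while Tnf was at -0.28 ± 0.15 and was not called. Of 24 cholesterol synthesis genes, 23 rose (24 adjusted over the list alone; camera adjusted p = 1.37e-21), with the sterol enzymes Sqle and Cyp51 up by 1.24 ± 0.10 and 1.25 ± 0.10. Of 38 alveolar macrophage identity genes, 9 rose and 14 fell (11 and 15 adjusted over the list alone; camera adjusted p = 0.0566; fry, down, adjusted p = 0.00102). camera called that list down without naive TRAM replicate 2 (adjusted p = 0.047) or 3 (adjusted p = 0.0439), or without day 7 TRAM replicate 2 (adjusted p = 0.0313) or 3 (adjusted p = 0.0358). Siglecf, a surface lectin of these cells, fell by 0.29 ± 0.07 and the scavenger receptor gene Marco fell by 0.34 ± 0.10, while the carbonic anhydrase gene Car4 rose by 1.22 ± 0.08. Of 40 monocyte and recruited macrophage genes, 30 rose and 4 fell (32 and 4 adjusted over the list alone; camera adjusted p = 3.62e-15). Markers of other cells moved in the same libraries: summed neutrophil markers went from 222 ± 10.3 to 482 ± 31.5 CPM. Of that sum, Mmp8 alone held 48.4 and 236.1 and Trem1 65.9 and 105.9, so both were already present in naive TRAM. Wfdc21 stood at 91.95 ± 13.2 CPM in day 7 TRAM and lay below Mmp8 in naive TRAM. B cell markers went from 174 ± 6.81 to 244 ± 10.7 CPM, of which Cd22 alone held 173 and 206. After Cd22, the immunoglobulin genes Igha and Igkc were highest in day 7 TRAM, at 19.52 and 8.998 CPM. In naive TRAM the gene after Cd22, Fcrla, stood at 0.6573 CPM. Of 10 T and NK cell markers, 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 1.59e-05). Their summed CPM nevertheless went down, from 222 ± 13.1 to 179 ± 16.1, of which Cd2 held 220.8 and 165.7. The next highest in day 7 TRAM, Il7r, stood at only 3.2 CPM. camera lost the list call in the fit of these 2 groups alone with the replicate number as a block (adjusted p = 0.109).

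The comparison of day 14 TRAM (n = 3) with naive TRAM (n = 4) asked what remained changed later. F13a1, a transglutaminase gene of monocytes and recruited macrophages, rose by 8.50 ± 0.35, from 4 to 1095 summed counts, and Mmp14 rose by 6.16 ± 0.31. Hpse, which encodes heparanase, rose by 5.97 ± 0.37, and Apoe, a lipid transport gene, by 1.70 ± 0.16. Marco fell by 0.99 ± 0.11, Car4 fell by 0.71 ± 0.09 and the heat-shock gene Hspa1b fell by 2.62 ± 0.34, while Siglecf was at 0.01 ± 0.07. In this comparison 804 genes were higher and 547 lower. Of the day 7 calls, 1010 were also called at day 14 in the same direction, against 171.6 for independent lists. In each of 20 simulations of unchanged groups the number was 0. Those groups were drawn from the mean of the same naive libraries, with no gene changed. That 0 was near certain in advance and cannot show what the shared naive libraries add to the overlap. With the naive libraries split so that the days shared none, the 6 splits gave 619 to 667, against 72.5 to 97 for independent lists.

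At day 14 the cell-cycle genes of TRAM were lower than in naive TRAM and the cholesterol genes had crossed to the other side. Of 50 cell-cycle genes, 47 fell (48 adjusted over the list alone; camera adjusted p = 2.84e-56), with the kinesin Kif11 at -1.21 ± 0.13, Mki67 at -0.98 ± 0.17 and Stmn1 at -0.88 ± 0.10. Of 24 cholesterol synthesis genes, 16 fell (18 adjusted over the list alone; camera adjusted p = 1.48e-12, adjusted p = 0.0999 with an estimated correlation), with Cyp51 at -0.69 ± 0.11. Of 40 monocyte genes, 22 rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p = 5.77e-16), and 8 of 16 MHC class II genes rose (11 adjusted over the list alone; camera adjusted p = 5.17e-13). Of 45 type I interferon genes, 16 rose (20 adjusted over the list alone; camera adjusted p = 4e-10), with Ifi209 up by 3.81 ± 0.24. Neutrophil markers summed to 291 ± 19.4 CPM against 222 ± 10.3 in naive TRAM, with Trem1, Mmp8 and Csf3r the highest in both groups. Cdkn2a rose by 1.60 ± 0.41 (adjusted p = 0.012), from 40 to 82 counts, a CPM ratio of 3.09 (exact 95% interval 2.09 to 4.63), and the call was lost without day 14 TRAM replicate 3 (adjusted p = 0.075). Cdkn2b was at 0.84 ± 0.39 (adjusted p = 0.22), Cdkn1a fell by 0.46 ± 0.09 and Lmnb1 fell by 0.81 ± 0.12. Of 31 arrest and senescence genes, 5 rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.248).

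The direct comparison of day 14 with day 7 TRAM (n = 3 against 4) gave 671 genes higher and 878 lower. F13a1 rose by 5.13 ± 0.25, Apoe by 1.32 ± 0.16, the eosinophil-type ribonuclease gene Ear1 by 1.88 ± 0.14 and Fabp1 by 1.59 ± 0.11. The inflammatory genes Il1b, Cxcl3, Lif and Osm fell by 2.60 ± 0.40, fell by 2.83 ± 0.28, fell by 2.17 ± 0.17 and fell by 1.94 ± 0.17. Mmp14 fell by 2.43 ± 0.17 and Car4 fell by 1.94 ± 0.09. Of 24 cholesterol synthesis genes, 23 fell (24 adjusted over the list alone; camera adjusted p = 5.57e-48), with Cyp51 at -1.94 ± 0.12 and Sqle at -1.73 ± 0.11. Of 34 inflammatory genes, 14 fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p = 2.25e-10). Of 50 cell-cycle genes, 1 fell and none rose (1 fell adjusted over the list alone; camera adjusted p = 0.516). Of 14 B cell markers, 8 fell (9 adjusted over the list alone; camera adjusted p = 1.81e-07), with Igha, an immunoglobulin heavy chain gene, at -6.53 ± 0.60, from 1115 to 9 counts. Cdkn2a was at -0.21 ± 0.37 (adjusted p = 0.79), so a fall from day 7 to day 14 was not called. Cdkn2b fell by 1.13 ± 0.36 (adjusted p = 0.044), a call lost without day 7 TRAM replicate 1 (adjusted p = 0.114), 2 (adjusted p = 0.101) or 3 (adjusted p = 0.0528), or day 14 TRAM replicate 1 (adjusted p = 0.0556), 2 (adjusted p = 0.0788) or 3 (adjusted p = 0.193). Of 31 arrest and senescence genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00464, adjusted p = 0.0623 with an estimated correlation). Of 34 p53 targets, 5 fell and 3 rose (5 and 4 adjusted over the list alone; camera adjusted p = 0.174; fry, down, adjusted p = 0.00409).

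TransAM and TRAM of the same day were compared to describe how the 2 populations differed within infected lungs. At day 7 (n = 4 each), TransAM held more Thbs1, a matrix glycoprotein gene, by 10.48 ± 0.28, and more C1qa, a complement component, by 9.68 ± 0.20. Apoe was higher by 9.29 ± 0.20, at 21500 ± 1890 against 34.4 ± 6.77 CPM, and the integrin gene Itgam by 6.37 ± 0.15. Marco was lower, at -7.52 ± 0.16, as were Siglecf at -4.58 ± 0.08, Car4 at -6.57 ± 0.11, the keratin gene Krt19 at -8.19 ± 0.14 and the lipid droplet gene Cidec at -7.76 ± 0.14. In all, 3585 genes were higher and 3648 lower in TransAM.

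By groups, 33 of 38 identity genes were lower and 2 higher in day 7 TransAM (33 and 2 adjusted over the list alone; camera adjusted p = 2.7e-21), with Pparg, a nuclear receptor needed by alveolar macrophages, at -1.70 ± 0.09 and Chil3, a chitinase-like gene, at -3.81 ± 0.12. Of 40 monocyte genes, 32 were higher and 3 lower (32 and 3 adjusted over the list alone; camera adjusted p = 3.42e-18), with Ccr2 at 1.87 ± 0.17 and F13a1 at 9.02 ± 0.22. Markers of other cells differed too: dendritic markers summed to 226 ± 7.89 CPM in TransAM against 84.2 ± 7.23 in TRAM. Of that sum, Bst2 held 119.6 against 35.43 CPM and Tcf4 54.41 against 13.4. The endothelial gene Vwf stood at 450.5 ± 37.6 against 187.7 ± 35.6 CPM and the platelet gene Pf4 at 39.15 ± 1.48 against 1.642 ± 0.875 CPM, and each held most of the sum of its marker list. Summed interstitial macrophage markers stood at 25770 ± 1870 CPM in TransAM, mostly Apoe, against 2652 ± 123 in TRAM, mostly Mrc1 (2575 CPM). That list shares Apoe and complement genes with the monocyte genes. Of 30 fatty acid oxidation genes, 26 were lower and 2 higher (26 and 2 adjusted over the list alone; camera adjusted p = 1.38e-10), with the peroxisomal enzyme gene Ehhadh at -3.79 ± 0.12. Of 24 cholesterol synthesis genes, 23 were lower (23 adjusted over the list alone; camera adjusted p = 2.13e-10, adjusted p = 0.176 with an estimated correlation), with Sqle at -1.37 ± 0.10. Among 50 cell-cycle genes, 48 were lower and 1 higher (48 and 1 adjusted over the list alone; camera adjusted p = 3.54e-17), with Bub1b at -2.23 ± 0.09. Of 47 lysosomal genes, 35 were higher and 5 lower (35 and 6 adjusted over the list alone; camera adjusted p = 1.17e-10), with the protease gene Ctsb at 2.25 ± 0.06. Cdkn2a and Cdkn2b were lower in TransAM, at -4.77 ± 0.57 and -5.04 ± 0.50. TRAM held 30.5 times (exact 95% interval 11.6 to 114) and 35 times (16.7 to 88) the CPM of these genes, from 122 against 4 and 245 against 7 counts, while Cdkn1a was at 0.05 ± 0.09 (adjusted p = 0.65). Among 31 arrest and senescence genes, 13 were higher and 10 lower (13 and 10 adjusted over the list alone; camera adjusted p = 0.245; fry, up, adjusted p = 6.91e-08).

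**Figure D3:**
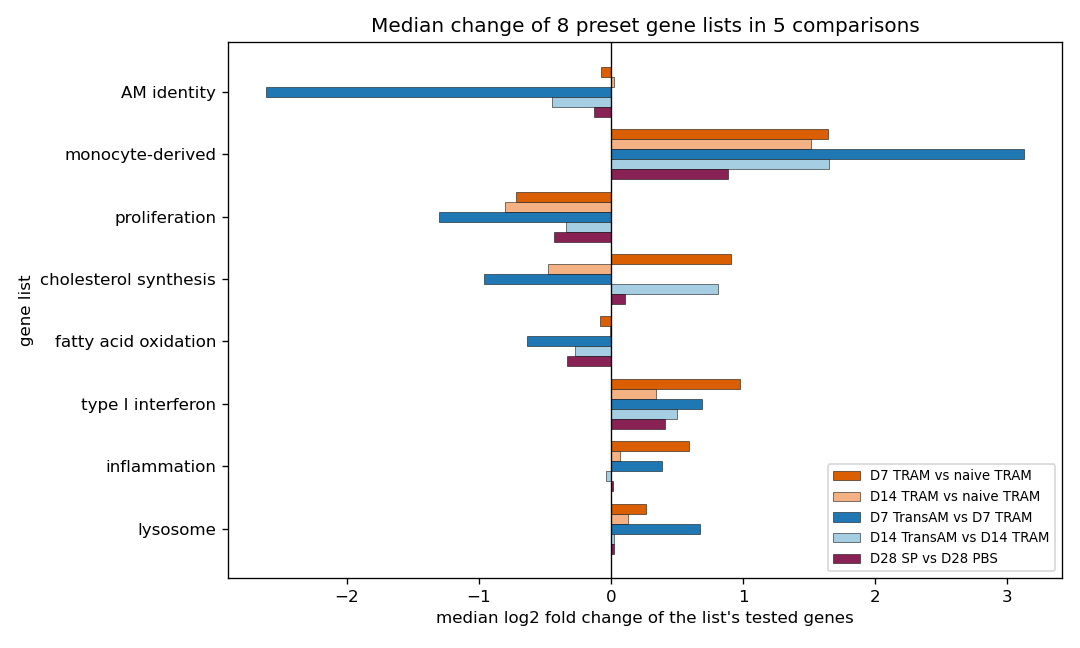
Median log2 fold change of the tested genes of 8 preset lists, 1 bar per comparison. The identity genes of TransAM against TRAM lay at -2.61 on day 7 and -0.45 on day 14, and the cholesterol synthesis genes at -0.96 and 0.81.

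At day 14 (n = 3 each), 1319 genes were higher and 1364 lower in TransAM than in TRAM. Thbs1 was higher by 4.32 ± 0.40, C1qa by 3.97 ± 0.32, Apoe by 2.54 ± 0.17, F13a1 by 2.42 ± 0.16 and Ccr2 by 2.42 ± 0.20. Marco was lower, at -4.41 ± 0.14, with Krt19 at -4.52 ± 0.12, the leptin receptor gene Lepr at -5.00 ± 0.21, Siglecf at -1.98 ± 0.08 and Car4 at -0.56 ± 0.10, while Pparg was at -0.17 ± 0.10 and was not called. Of 38 identity genes, 21 were lower and 2 higher (22 and 3 adjusted over the list alone; camera adjusted p = 1.75e-18), and of 40 monocyte genes, 32 were higher and 1 lower (33 and 2 adjusted over the list alone; camera adjusted p = 3.31e-22). Of 24 cholesterol synthesis genes, 18 were higher (20 adjusted over the list alone; camera adjusted p = 3.41e-16, adjusted p = 0.102 with an estimated correlation), with Cyp51 at 1.25 ± 0.12. Of 30 fatty acid oxidation genes, 15 were lower and 1 higher (15 and 1 adjusted over the list alone; camera adjusted p = 3.97e-10), with the thiolase gene Acaa1b at -4.34 ± 0.17. Of 50 cell-cycle genes, 18 were lower (24 adjusted over the list alone; camera adjusted p = 4.86e-09, adjusted p = 0.115 with an estimated correlation), with Kif23 at -0.65 ± 0.10. Among markers of other cells, neutrophil markers summed to 377 ± 26.8 CPM in TransAM against 291 ± 19.4 in TRAM and dendritic markers to 108 ± 4.3 against 78.1 ± 8.71. The dendritic sum was mostly Bst2 and Tcf4, at 39.13 and 51.24 CPM in TransAM against 35.51 and 21.03 in TRAM. T and NK cell markers, mostly Cd2, ran the other way, at 65.25 ± 4.17 against 201.3 ± 30 CPM. Interstitial macrophage markers, mostly Mrc1, stood at 3620 ± 82.9 against 2857 ± 235 CPM. Endothelial and stromal markers, mostly Vwf, stood at 248.4 ± 21.2 against 184.5 ± 11.7 CPM. For Cdkn2a, day 14 TransAM held 2 counts in all and TRAM 82, a CPM ratio of TRAM to TransAM of 43 (exact 95% interval 11.5 to 361). Cdkn2b was at -3.28 ± 0.56, from 9 against 87 counts. Of 31 arrest and senescence genes, 2 were higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.928).

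Within TransAM, day 14 (n = 3) was compared with day 7 (n = 4). The ribonuclease gene Ear1 rose by 7.41 ± 0.23, Cidec by 5.74 ± 0.15, Plet1 by 4.77 ± 0.09, Car4 by 4.07 ± 0.10, Chil3 by 3.17 ± 0.12, Siglecf by 2.89 ± 0.08 and Marco by 2.46 ± 0.20. Stab1, a scavenger receptor gene, fell by 7.56 ± 0.24, Ly6c2, a marker of classical monocytes, fell by 7.48 ± 0.24, C1qa fell by 6.84 ± 0.18, Apoe fell by 5.43 ± 0.19 and the acute-phase gene Saa3 fell by 8.80 ± 0.70. Of 38 identity genes, 31 rose and 3 fell (31 and 3 adjusted over the list alone; camera adjusted p = 2.99e-19). Cell-cycle genes rose as well: of 50, 44 rose and 1 fell (44 and 1 adjusted over the list alone; camera adjusted p = 4.59e-13), with Kif23 up by 1.82 ± 0.11. Of 40 monocyte genes, 31 fell and 4 rose (31 and 4 adjusted over the list alone; camera adjusted p = 8.85e-18), and of 47 lysosomal genes, 35 fell and 4 rose (36 and 4 adjusted over the list alone; camera adjusted p = 1.06e-16). Of 30 fatty acid oxidation genes, 25 rose and 2 fell (25 and 3 adjusted over the list alone; camera adjusted p = 1.55e-08). Of 14 B cell markers, 12 fell in the same libraries (14 adjusted over the list alone; camera adjusted p = 2.77e-06). Interstitial macrophage markers went from 25770 ± 1870 to 3620 ± 82.9 CPM. That sum was mostly Apoe at day 7 and mostly Mrc1 at day 14 (2866 CPM), and Mrc1 stood at 2700 CPM in naive TRAM as well. Dendritic markers went from 226 ± 7.89 to 108 ± 4.3 CPM, and erythroid and platelet markers, mostly Pf4 at day 7, from 42.6 ± 1.3 to 1.82 ± 0.258 CPM. Of the dendritic sum, Bst2 held 119.6 CPM at day 7 and 39.13 at day 14, and Tcf4 held 54.41 and 51.24. Among 31 arrest and senescence genes, 13 fell and 6 rose (13 and 6 adjusted over the list alone; camera adjusted p = 0.00811, adjusted p = 0.0808 with an estimated correlation). In all, 3058 genes rose and 2997 fell.

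Against naive TRAM (n = 4), TransAM had 7891 genes called at day 7 (n = 4) and 4233 at day 14 (n = 3). Apoe was higher by 9.67 ± 0.20 at day 7 and 4.24 ± 0.17 at day 14, and Spp1, which encodes osteopontin, by 3.84 ± 0.14 and 2.86 ± 0.14. Marco was at -7.86 ± 0.16 and -5.39 ± 0.14, Siglecf at -4.87 ± 0.08 and -1.97 ± 0.08, and Car4 at -5.34 ± 0.10 and -1.27 ± 0.09. Of 50 cell-cycle genes, 49 were lower and 1 higher on both days (49 and 1 adjusted over the list alone; camera adjusted p = 1.27e-23 and 3.21e-34), with Mki67 at -1.65 ± 0.16 and -1.31 ± 0.17. Cdkn2a at day 7 was at -2.96 ± 0.66 and Cdkn2b at -3.08 ± 0.58. At day 14 naive TRAM held 13.9 times the Cdkn2a CPM of TransAM (exact 95% interval 3.61 to 119), from 40 against 2 counts, and Cdkn2b was at -2.44 ± 0.57.

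A test of the change of the TransAM to TRAM difference between days 7 and 14 gave 2009 genes with a positive and 1746 with a negative change. The difference rose by 6.01 ± 0.14 for Car4, 3.33 ± 0.16 for Chil3, 3.11 ± 0.23 for Marco and 2.60 ± 0.11 for Siglecf, and fell by 6.75 ± 0.24 for Apoe, fell by 5.70 ± 0.67 for C1qa and fell by 4.17 ± 0.14 for Gpnmb, a membrane glycoprotein gene. All 24 cholesterol synthesis genes had a positive change (24 adjusted over the list alone; camera adjusted p = 1.65e-24), with Cyp51 at 2.51 ± 0.16 and Hmgcs1 at 2.05 ± 0.19. Of 38 identity genes, 29 had a positive and 4 a negative change (32 and 4 adjusted over the list alone; camera adjusted p = 2.96e-24), and of 50 cell-cycle genes, 38 had a positive and 1 a negative change (43 and 1 adjusted over the list alone; camera adjusted p = 1.37e-14). For the difference in Cdkn2a no change was called (adjusted p = 0.83), nor for Cdkn2b (adjusted p = 0.18), which was called without day 14 TransAM replicate 1 (adjusted p = 0.0446).

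At day 28 (n = 3 each), cells from infected lungs were compared with cells from lungs given PBS. F13a1 rose by 7.02 ± 0.25, from 0.373 ± 0.0501 to 49.6 ± 9.83 CPM, Mmp14 by 3.72 ± 0.21 and Spp1 by 2.21 ± 0.18. Marco fell by 4.51 ± 0.40, from 520 ± 200 to 22.9 ± 10.1 CPM, Lepr fell by 3.67 ± 0.25, Acaa1b fell by 3.22 ± 0.19, Pdk4, a mitochondrial kinase gene of fuel choice, fell by 2.57 ± 0.19, and Siglecf fell by 0.86 ± 0.12. Cdkn2b fell by 2.32 ± 0.33 (adjusted p = 0.002), from 164 to 29 counts. Cdkn2a fell by 1.82 ± 0.43 (adjusted p = 0.025), from 85 to 21 counts, and lost its call without PBS replicate 3 (adjusted p = 0.102), SP replicate 2 (adjusted p = 0.0915) or SP replicate 3 (adjusted p = 0.115). In all, 918 of 13314 genes were higher and 868 lower, 1786 together. That count depended on single libraries: it was 5235 without PBS replicate 1, 951 without PBS replicate 3, 927 without SP replicate 1 and 974 without SP replicate 3.

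Of 36 monocyte genes, 19 rose at day 28 and none fell (22 rose and 3 fell adjusted over the list alone; camera adjusted p = 1.27e-09, adjusted p = 0.177 with an estimated correlation). Of 38 identity genes, 15 fell and 5 rose (15 and 6 adjusted over the list alone; camera adjusted p = 0.000884, adjusted p = 0.208 with an estimated correlation). Of 50 cell-cycle genes, 18 fell (27 adjusted over the list alone; camera adjusted p = 1.27e-09, adjusted p = 0.277 with an estimated correlation), with the mitotic genes Cdc20 and Ube2c at -1.28 ± 0.12 and -1.33 ± 0.20, while Mki67 was at -0.25 ± 0.12 and was not called. Of 31 arrest and senescence genes, 7 fell and 1 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.235). Of 18 lung epithelial markers, 16 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 5.77e-10, adjusted p = 0.208 with an estimated correlation), with the surfactant protein gene Sftpc at -5.83 ± 0.22 and the club cell gene Scgb1a1 at -5.65 ± 0.45. The epithelial markers summed to 806 ± 288 CPM after PBS and 164 ± 16.9 after SP, and erythroid and platelet markers to 99.6 ± 54.2 and 4.07 ± 2.63 CPM. T and NK cell markers, mostly Cd2, were lower after SP too, at 316 ± 37.3 and 122 ± 17.7 CPM. Interstitial macrophage markers, mostly Mrc1, were higher after SP, at 1825 ± 311 and 2826 ± 272 CPM. So were dendritic markers, at 173 ± 28.2 and 225 ± 10.4, and B cell markers, mostly Cd22, at 159 ± 5.64 and 211 ± 8.26.

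The day 28 libraries were also read with gene sets taken from the earlier libraries. Of the 200 genes that were most raised in day 14 TransAM over TRAM, 196 were tested, 154 rose at day 28 and none fell, with a median of 1.79 (camera adjusted p = 2.79e-57). Of the 200 most lowered, 153 fell and none rose, with a median of -1.02 (camera adjusted p = 3.4e-52). Of the 200 most raised in day 14 TRAM over naive TRAM, 198 were tested, 160 rose and 2 fell, with a median of 1.79 (camera adjusted p = 1.18e-59), and of the 200 most lowered, 76 fell and 1 rose, with a median of -0.46 (camera adjusted p = 2.51e-17). All 4 held with an estimated correlation, with adjusted p of 0.00603 for the first 3 sets and 0.0407 for the last. Of the list calls printed above, those without an estimated-correlation p beside them also held with it.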

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

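The tests of the Cdkn2 and monocyte gene patterns were chosen after those results were seen, as was the count of draws by the days exchanged, and the second form of the admixture test was set after the outcome of its first form and the shares of single genes had been seen. The reading of the day 28 share from raised genes was chosen after the share from lowered genes and single raised genes were seen. The other day 28 tests were written before the values they measure were seen, though after the day 28 pattern itself, and the splits of the libraries were planned.

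Of 210 combinations of a named gene and a group of 4 libraries, 9 had 1 library far from the other 3, its gap to the nearest taking most of the range of the group (the share is given for each). Chance alone gives this in about 1 in 20, so 9 are no more than chance would bring. In day 7 TRAM these were Mki67 (0.945; replicate 2 at 95.6 CPM, the others at 159 to 163), Il21r (0.893; replicate 3 at 2.17, the others at 6.12 to 6.6), Ltf (0.92; replicate 4 at 7.58, the others at 2.39 to 2.8), Slfn5 (0.907; replicate 1 at 6.52, the others at 4.47 to 4.66) and Bcl2 (0.861; replicate 1 at 0, the others at 0.419 to 0.487). In naive TRAM they were Car4 (0.96; replicate 3 at 605, the others at 691 to 694) and Isg15 (0.865; replicate 2 at 2.28, the others at 1.38 to 1.5). In day 7 TransAM they were Hmgcs1 (0.98; replicate 2 at 143, the others at 110) and Cdkn2b (0.956; replicate 3 at 0.244, the others at 0.0699 to 0.0776). Day 7 TRAM replicate 2 also stood apart over genes in general, so its Mki67 value need not be chance. Its chi-square per degree of freedom against replicates 1, 3 and 4 was 19.92, 27.02 and 20.18. Between those replicates it was 5.315 to 7.432.

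The difference between TransAM and TRAM was not the same on days 7 and 14, by a test of the change itself, for 3755 genes. The genes named for it were Car4 (6.01), Chil3 (3.33), Marco (3.11), Siglecf (2.60), Cyp51 (2.51), Hmgcs1 (2.05), Kif23 (1.55) and Pparg (1.53) with a positive change. Apoe (-6.75), C1qa (-5.70), Gpnmb (-4.17) and Ctsb (-2.06) had a negative one.

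For the comparisons with 35 splits of the libraries into groups of the same sizes, only the real split, 1 of 35, called as many genes as itself. The real split and the highest other were 3436 and 2 for day 7 TRAM against naive TRAM, 1225 and 63 for day 14 TRAM against naive TRAM, and 962 and 108 for day 14 against day 7 TRAM. They were 6986 and 0 for day 7 TransAM against TRAM, 5984 and 1 for day 14 against day 7 TransAM, 8251 and 0 for day 7 TransAM against naive TRAM, and 4202 and 0 for day 14 TransAM against naive TRAM. For these the share is under 0.05, and 1 of 35 is the smallest that so many splits can give. A split that mixes the groups also widens the spread within them, so few calls there were likely in advance. The counts thus argue against a chance split of the samples but do not exclude it. For day 14 TransAM against TRAM (1720; highest other 0) and for day 28 (1786; highest other 0), 10 splits are too few for a share under 0.05. For the change between days, 1 of 100 draws, the real one, reached 3430, but the highest other reached 3361 and the next 3347. In the 3 draws that kept the days of all TransAM libraries, the real one included, the counts were 3347 to 3430, though 4 TRAM libraries had another day in the other draws of these. Every draw that gave TransAM libraries another day called at most 41 genes, so the count follows the days of TransAM and shows little about those of TRAM.

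The first pattern weighed was the shift of infected day 28 cells towards the day 14 TransAM profile. RNA of epithelial and red blood cells in the PBS libraries would have raised the 200 lowered genes there, but their median log2 ratio of PBS to naive TRAM was 0.02 (quartiles -0.43 and 0.50), against -1.04 for SP, in libraries of tables scaled apart. The median covers the set as a whole and leaves the genes at or above the upper quartile open. Thinning all 6 libraries to the smallest total left the median of the raised set at 1.78, but the totals differed by at most 1.21 times and the values were already scaled to them, so this decides nothing about deeper PBS libraries. Cells with the day 14 TransAM profile among the infected day 28 cells remain open and are consistent with a median implied share of 75% by the lowered genes (quartiles 54 and 91.4) and 54.6% by the raised genes. The raised genes spread widely (quartiles 31.8 and 75.4; Apoe 21.2%, F13a1 37.3%), so no single share holds for all genes, the reading assumes that such cells keep that profile to day 28, and a change of resident cells themselves was not tested. The genes most raised in day 14 TRAM over naive TRAM rose at day 28 by the same median (1.79) as those raised in TransAM. For raised genes the shift was thus not particular to the TransAM profile. The lowered sets differed, at medians of -0.46 for TRAM and -1.02 for TransAM.

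The second pattern was the rise of Cdkn2a and Cdkn2b in day 7 TRAM. TransAM cells in the TRAM gate are argued against, since the higher of the 2 log2 changes in day 7 TransAM against naive TRAM was -2.96. Sampling noise of few counts is argued against by the lower bound of the count ratios, 2.48. For a p53 transcriptional response, the upper 95% bound for Cdkn1a was 0.13 and camera did not call the p53 targets, but fry called them up (adjusted p = 0.0336), so such a response without Cdkn1a stays open. A higher share of TRAM expressing these genes, as in senescent cells, and a change in every cell remain open, and bulk counts cannot part them.

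The third pattern was the rise of monocyte genes in TRAM, where TransAM cells in the TRAM gate were the technical explanation. In the first form of the test, which took the upper quartile of the share implied by 200 genes (20.7% at day 7 and 48% at day 14), 5 of 30 risen genes at day 7 and 0 of 22 at day 14 rose by over 3 times what that share would bring. In the second form, which took the lower quartile over abundant TransAM transcripts (2.62% at day 7, 23.6% at day 14), these were 17 of 30 and 1 of 22. At day 7 the 2 forms part: Apoe, C1qa and Thbs1 allow shares of 0.0368%, 0.118% and 0.0162% of day 7 TransAM cells, while Mmp14 needs 19.3%. That argues against cells with the mean day 7 TransAM profile as the whole cause. It does not cover cells with a later profile in the TRAM gate. In day 14 TransAM, Apoe, C1qa and Thbs1 were lower than at day 7 (log2 changes of -5.43, -6.84 and -6.28). At day 14 single genes part as well (Thbs1 0.901%, C1qa 5.94% and Ccr2 9.13%, against H2-Aa 45.9% and Cd74 53.4%), and the second form rests on 16 abundant genes there (121 at day 7), so TransAM cells in the TRAM gate remain open and may account for part of that rise.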

How the results depend on the processing

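All alternatives were planned, and no test here was chosen after the results were seen. Among the named genes, 3272 results kept direction and side of the threshold, 44 lost and 19 gained a call, and none reversed. Many of these genes were picked for a large change or a small adjusted p in the same data, so their calls were likely to hold. limma-voom with quality weights was run for the counts of called genes only. Among the lists, 3506 results kept direction and side of the threshold, 153 lost and 115 gained a call, and 1 reversed. DESeq2 size factors moved the median log2 change of a comparison by at most 0.025 and changed no call of a named gene. A correlation estimated from the data ended 85 list calls, and fry gained 68. Counts of called genes stayed within 1.5 times of the reported ones except as follows, and the cause was not tested where none is given. limma-voom called 3550 genes for day 14 TRAM against naive TRAM (1351 reported), 3171 for day 14 against day 7 TRAM (1549) and 7476 for day 28 (1786). Without a count filter day 28 gave 3753. An added threshold of 1 on the absolute log2 change, by its construction, left 968, 444 and 437 genes for day 7 TRAM against naive, day 14 TRAM against naive and day 14 against day 7 TRAM. It left 2806, 1030 and 2067 for TransAM against TRAM at day 7 and day 14 and for TransAM between days, 3453 and 1686 for day 7 and day 14 TransAM against naive TRAM, 1519 for the change between days and 923 for day 28. Fits of only the groups compared, with fewer libraries, called 962 for day 14 against day 7 TRAM and 1720 for day 14 TransAM against TRAM. Splitting the naive libraries into 2 sets of 2, with fewer libraries per fit, gave a median of 633.5 day 7 calls kept at day 14 (1010).

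The replicate numbers did not clearly pair the samples: correlations of same-numbered deviations ran from -0.308 to 0.527. In no comparison did all exceed 0.1 or every sample correlate best with its own number. At day 28, 2 of 3 SP samples correlated best with the PBS sample of their own number (0.178 and 0.527), so pairing there stays unresolved. Fits with the replicate number as a block also held only the groups compared. They called 765 genes for day 14 TRAM against naive TRAM (1225 in the same fit without the block), 834 for day 14 against day 7 TRAM (962 without it) and 3355 for day 28 (1786 without it), and other counts stayed within 1.5 times of the reported ones. In these fits the T and NK cell list of day 14 TRAM against naive TRAM reversed (median -0.144, camera adjusted p = 0.483). They gave no value for the erythroid and platelet list of day 14 TransAM against TRAM. Whether the block or the smaller set of libraries did this was not tested.

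Leaving out 1 library at a time gave 2958 to 3344 genes for day 7 TRAM against naive TRAM, 926 to 1363 for day 14 TRAM against naive TRAM, 1077 to 1694 for day 14 against day 7 TRAM, 6598 to 6996 and 1924 to 3073 for TransAM against TRAM at day 7 and day 14, and 5145 to 5744 for TransAM between days. It gave 7363 to 7553 and 3555 to 3914 for day 7 and day 14 TransAM against naive TRAM, 3218 to 4213 for the change between days, and 727 to 1106 kept calls. For day 28 it gave 927 (without SP replicate 1) to 5235 (without PBS replicate 1), with 951 without PBS replicate 3 and 974 without SP replicate 3. The medians of the 4 day 28 sets ran from 1.667 to 1.843, -1.037 to -0.965, 1.701 to 1.824 and -0.52 to -0.42. At 3 libraries per group, 28.4% of 1.5-fold changes were recovered in simulated day 28 counts, so small changes are largely missed there.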

Other observations

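The test of how TransAM approach TRAM and the overlaps between day 14 and day 28 below were chosen after the values were seen. Day 7 TRAM also held more transcripts of phagocytic and lysosomal genes than naive TRAM. Of 35 phagocytosis genes, 25 rose and 2 fell (26 and 2 adjusted over the list alone; camera adjusted p = 9.54e-12), with the scavenger receptor gene Msr1 up by 2.38 ± 0.11, and of 47 lysosomal genes, 30 rose (35 adjusted over the list alone; camera adjusted p = 4.02e-14), with the tetraspanin gene Cd63 up by 2.04 ± 0.09. The cystine transporter gene Slc7a11 rose by 2.72 ± 0.13, the glycolytic enzyme gene Hk2 by 1.22 ± 0.10, the growth arrest gene Gadd45a by 2.06 ± 0.25 and the arginine-degrading enzyme gene Arg1 by 2.54 ± 0.39.

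In infected day 28 cells, interferon-inducible genes went both ways. Isg15 fell by 1.44 ± 0.33 (adjusted p = 0.02), a call lost without PBS replicate 3 (adjusted p = 0.0657) or SP replicate 1 (adjusted p = 0.0934), 2 (adjusted p = 0.0548) or 3 (adjusted p = 0.0872). Of 42 type I interferon genes, 11 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 7.06e-05, adjusted p = 0.277 with an estimated correlation). Ifi209 rose by 3.82 ± 0.20, the secretory kinase gene Fam20c by 3.98 ± 0.19, the MHC class I activator gene Nlrc5 by 1.93 ± 0.14, the costimulatory gene Cd86 by 1.67 ± 0.15 and the necroptosis kinase gene Ripk3 by 1.25 ± 0.13. The adhesion gene Cd2 fell by 1.52 ± 0.14 and Cd36 fell by 1.90 ± 0.10.

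Genes called at day 28 were compared with those of earlier comparisons that share no library with it. With day 14 TransAM against TRAM, 1075 were called in the same direction (168.3 for independent lists) and 11 in opposite directions, and with day 14 TRAM against naive TRAM, 585 (86.68) and 26. With day 14 TransAM against naive TRAM these were 1359 (262.4) and 13, and with day 7 TRAM against naive TRAM 783 (217.5) and 118, the latter against 214.5 for independent lists.

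A hypothesis that TransAM take on the TRAM profile between day 7 and day 14 was tested on 1345 genes called at day 7 with an absolute log2 difference of 2 or more. The median ratio of the day 14 to the day 7 difference was 0.4 (quartiles 0.21 and 0.59). The median log2 change of TransAM towards TRAM was 2.08, and that of TRAM towards TransAM was 0. These values are consistent with the hypothesis, but genes picked for a large day 7 difference tend to show a smaller one later, and the loss of some cells and the arrival of others would give the same values.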
